A study of Amphimedon queenslandica with 43 samples.

How the data were processed

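Transcripts were measured in 43 individually sequenced larvae of the demosponge Amphimedon queenslandica, per the labels. RNA of each larva was isolated with TRIzol and amplified and sequenced by CEL-Seq2, per the labels' protocols. CEL-Seq2 is a barcoded protocol for very small RNA inputs that primes on the poly(A) tail and amplifies by in vitro transcription, so a read marks the 3' end of a transcript. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here.

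The authors deposited a table of raw counts per transcript model and larva, with 47411 models, of which 44016 have identifiers starting with Aqu2.1 and 3395 identifiers starting with TCONS. No count in any larva was found for 8897 of them. Per the file header and file name, features of the spike-in RNA and of bacteria had been left out before deposit. A second table that the authors deposited holds size-factor normalized signal values for 28061 models. Each of its values equalled the raw count divided by 1 factor per larva, and those factors differed by at most 2.09e-06% from median-of-ratios size factors computed here from the counts. The models in it had a count in at least 7 larvae, and those left out of it had a count in at most 6. It served only for that check. The highest deposited count was 8192, reached 23 times, and the most abundant model, Aqu2.1.25583_001, had at least 8000 counts in 41 of the 43 larvae. The counts of the most abundant models were therefore limited from above, and their fold changes between larvae may understate the change.

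The files do not pair the identifiers with gene names, and 0 of the identifiers matched the reference gene table. For that reason the gene lists fixed before the data were examined (photoreception and clock, germline and stem cell, skeleton-forming, contractile and epithelial, ciliary, yolk and the others) were not analysed here, nor were cell type markers, and no function is given for any model. The rule for naming genes, fixed at the same time, then takes at most 2 models that rose and 2 that fell in each comparison, ranked by the size of the log2 fold change among models with an adjusted p below 0.05 and a mean of at least 20 CPM (counts scaled to the library total) in the higher group. The rule gave 46 entries over 33 models. The results below describe only some of these entries, not always the highest-ranked, and 38 of the 46 lost their call with limma voom. Models counted by 3' tags can share reads with near-identical copies, which the sources used here do not settle.

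Groups came from the sample titles, with 7 larvae in each group and 8 in the day-night group at 9 hours post emergence (hpe). Total counts per larva ran from 1890954 to 3927366, with a median of 2869317. Total counts were compared between groups with exact two-sided permutation tests of mean log10 totals, adjusted by the Benjamini-Hochberg method over 9 comparisons. No replicate pair agreed within sampling noise, since the lowest chi-square per degree of freedom over 133 pairs was 13.0. The replicates are separate larvae, per the labels. The labels give no parent and no batch, so p-values measure the spread between these larvae.

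Models were tested with edgeR 4.0.16 (R 4.3.3). Low counts were removed with filterByExpr by group at its minimum count of 10, which left 14188 models. Libraries were scaled with TMM, dispersions were estimated robustly, and 1 quasi-likelihood model with a mean for each of the 6 groups was fitted to all larvae. A model counted as changed at a Benjamini-Hochberg adjusted p below 0.05, with no fold threshold. The 12 comparisons were 9 against 1 hpe within each regime, the regimes against each other at each age, and the difference of the age change between regimes. Standard errors were taken from the fold change and the square root of the F statistic. Levels are CPM as mean ± SD. Where a group had no count of a model, the fold is given as a lower bound from a floor of 3 counts over the group. With 1 to 3 counts in a group, the ratio of pooled counts per library size is given with its 95% exact Poisson interval. Such floors and intervals cover counting error only.

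The fit was tested on simulated data in which 200 of the 14188 models were changed. For 9 against 1 hpe in day-night larvae 40% of the 2-fold and 74% of the 4-fold changes were recovered, for constant light against day-night at 9 hpe 33% and 73%, and for the difference of the age change between constant-light and constant-dark larvae 22% and 51%. Between 2 and 7 unchanged models were called per comparison, and 0 changes were called in the wrong direction. The counts were drawn independently for each model and larva from the fitted dispersions. Alike larvae and models that move together were not simulated, so these rates may not hold for the real counts.

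An age score was computed for each larva as the mean log2 CPM of models higher at 9 hpe minus the mean log2 CPM of models lower at 9 hpe, with a prior count of 2. The models came from the regime that gave no larva to the comparison. All larvae shared 1 fit, so the larvae scored also entered the filter and the spread used to choose the models. The same holds for the tests on groups of called models, and the permutation p-values take no account of it. Scores were compared with exact two-sided permutation tests, and differences of the age change by permuting regime labels within each age. The score, the clustering of larvae and the tests on groups of called models were chosen after the data were seen. For the clustering, age means were removed from log2 CPM and the 500 most variable models above a mean of 50 CPM were joined by average linkage on 1 minus Pearson's correlation, with merges up to a height of 0.9. Other recipes were looked at before this one was kept, and 2 of them are compared with it under the other observations.

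The alternatives chosen before the data were examined were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, no filter on low counts, a mean of at least 10 CPM, only the groups compared in the fit, the replicate number as a block, libraries of at least 0.5 times the median total, limma 3.58.1 voom with sample quality weights, and untransformed library totals. Added after the data were seen were the cluster of the larva as a term, 11 surrogate variables (sva 3.50.0) as terms, counts corrected for the ceiling, counts thinned to 1 total per larva, fits without certain alike larvae, and fits leaving out each larva in turn. The alternatives planned for the gene lists were not run. For each comparison 100 splits of the larvae, the real one included, were fitted in the same way.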

Results

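The series asked how the light around a larva of the sponge Amphimedon queenslandica bears on the transcripts it holds as it becomes competent to settle. Larvae collected within 30 minutes from 11 am were placed by 0.5 hours post emergence (hpe) under a natural day-night regime, under a constant dark regime, in which a neutral density filter passed 6.6% of the ambient daylight, or under constant light from a fluorescent tube. Whole larvae were taken at 1 hpe, held to be before competence to settle, and at 9 hpe, held to be the age of competence. No settlement data were used here, so whether larvae of each regime were competent at 9 hpe was not tested. Transcript counts were obtained from 43 larvae, each sequenced by itself. There were 7 larvae per regime at 1 hpe, 8 day-night larvae at 9 hpe, and 7 larvae in each of the other groups at 9 hpe.

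Total counts per larva at 1 hpe averaged 2959936 ± 427228 in day-night (SD, n = 7), 3143107 ± 462342 in constant dark (n = 7) and 3164866 ± 240220 in constant light (n = 7). At 9 hpe they averaged 2489125 ± 452797 in day-night (n = 8), 2508172 ± 462633 in constant dark (n = 7) and 3212744 ± 383430 in constant light (n = 7). Constant-light larvae at 9 hpe had 1.29 times the total of day-night larvae (exact two-sided permutation p = 0.00730, adjusted p = 0.0446 over 9 comparisons) and 1.28 times that of constant-dark larvae (exact permutation p = 0.00991, adjusted p = 0.0446). Both adjusted values became 0.0551 on untransformed totals. The other 7 comparisons of totals did not pass. Counts were found for 19319 to 23793 transcript models per larva.

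Age separated the larvae on the first principal component of log2 CPM (counts scaled to the library total), which held 9.65% of the variance. Larvae at 1 hpe lay between -59.9 and -13.7 and larvae at 9 hpe between 6.26 and 53.0. At 9 hpe the constant-light larvae ended at 29.4, below the lowest day-night larva at 33.02. On the second component, with 6.07% of the variance, 8 larvae lay at or below -38.9 and all other larvae at or above -12.1. Of those 8 larvae, 3 came from constant dark at 1 hpe, 1 from constant light at 1 hpe and 4 from constant light at 9 hpe, so that 0 of the 15 day-night larvae were among them. These 8 larvae also formed 1 of 9 clusters of at least 2 larvae with alike profiles, which are described under the other observations.

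**Figure D1:**
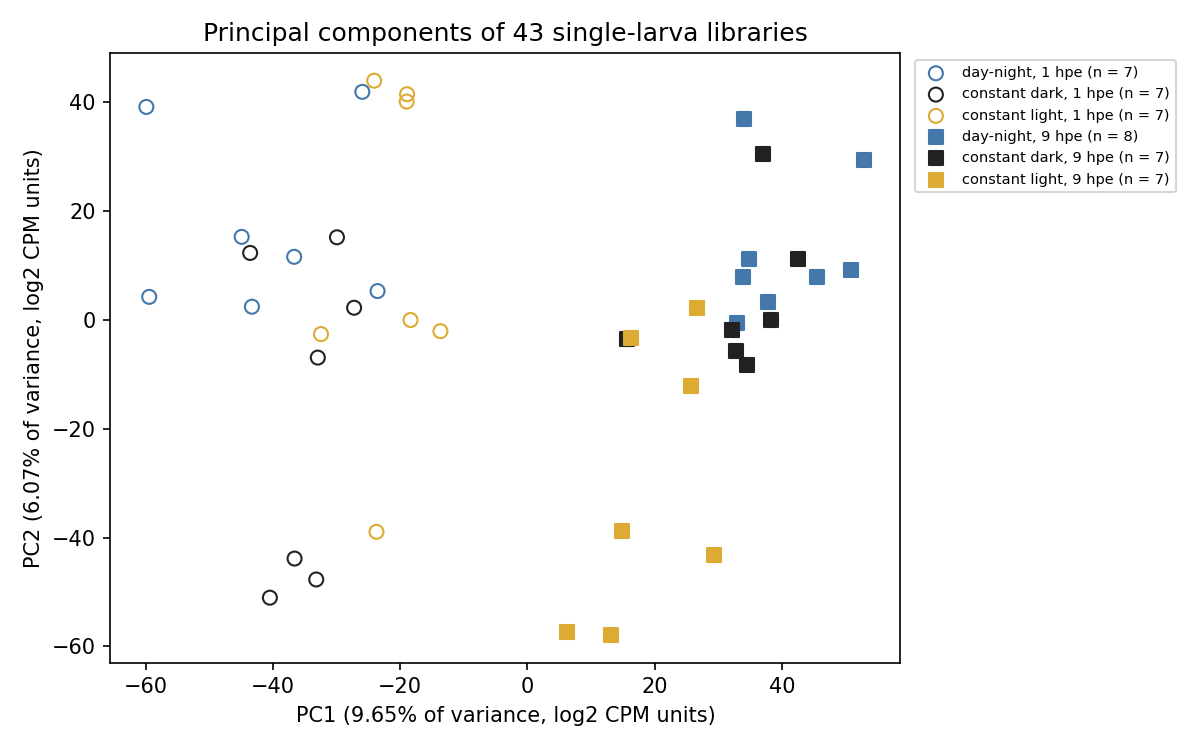
Position of each larva on the first principal component of log2 CPM (horizontal axis) and on the second (vertical axis), with open circles for 1 hpe, filled squares for 9 hpe, and the regime given by colour. Larvae at 1 hpe all lie to the left of those at 9 hpe, and 8 larvae from constant dark and constant light lie at the bottom, at or below -38.9 on the second component.

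All larvae were collected at the same time of day, so age at sampling cannot be told apart from time of day. In regimes under natural light, the ambient light may also have changed with the hour. In day-night larvae, 3127 of 14188 tested models changed between 1 and 9 hpe. Of these, 1410 rose and 1717 fell, and 1361 changed at least 2-fold. Aqu2.1.10425_001 rose from 0.707 ± 0.353 CPM (n = 7) to 112 ± 83.3 CPM (n = 8), a log2 fold change of 7.25 ± 0.84 SE (edgeR quasi-likelihood F test, adjusted p = 1.53e-08). Ranked above it, Aqu2.1.41196_001 rose from 3 counts in all, in 2 of 7 larvae, to 46.7 ± 80.0 CPM, in 5 of 8 larvae (edgeR adjusted p = 0.0286). That is a ratio of 344 with a 95% counting interval of 117 to 1669. Its fitted log2 fold change was 7.88 ± 2.67 SE, and 5.06 ± 4.06 SE with the cluster of the larva as a term (adjusted p = 0.456). Limma voom gave an adjusted p of 0.623 (0.00740 to 0.972 over the alternatives). Aqu2.1.33376_001 fell from 428 ± 546 CPM to 7.08 ± 6.43 CPM, a log2 fold change of -5.91 ± 1.26 SE (adjusted p = 0.000468, 0.162 with limma voom, and 5.89e-08 to 0.549 over the alternatives). Aqu2.1.04208_001 fell from 70.8 ± 98.1 CPM to 0.922 ± 1.12 CPM, a log2 fold change of -6.12 ± 1.91 SE (adjusted p = 0.0171). It was -2.96 ± 2.09 SE with the cluster of the larva as a term (adjusted p = 0.386). Over the alternatives the adjusted p ran from 0.000886 to 0.428, the latter with limma voom. With that cluster term 2059 models changed, and with 11 surrogate variables as terms 811.

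In constant-dark larvae, 2838 models changed with age, 1332 of them upwards and 1506 downwards. Aqu2.1.30110_001 rose from 0.888 ± 1.22 CPM (n = 7) to 39.8 ± 47.0 CPM (n = 7), a log2 fold change of 5.38 ± 1.33 SE (edgeR adjusted p = 0.00319). Aqu2.1.00853_001 fell from 47.2 ± 38.96 CPM to 0.437 ± 0.642 CPM, a log2 fold change of -6.48 ± 1.75 SE (adjusted p = 0.00677). The cluster term made these 3.95 ± 1.64 SE (adjusted p = 0.142) and -5.03 ± 1.66 SE (adjusted p = 0.0587). Limma voom gave adjusted p of 0.145 and 0.114 (over the alternatives 2.63e-05 to 0.204 and 0.000160 to 0.235). With the cluster term 1087 models were called, 980 of them among the 2838. Without the 8 larvae low on the second component it was 1732, and with surrogate variables 379.

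In constant-light larvae, 867 models changed with age, 373 upwards and 494 downwards. TCONS_00000986 rose from 2 counts in all, in 2 of 7 larvae, to 30.0 ± 21.6 CPM in 6 of 7 larvae (edgeR adjusted p = 0.0235), a ratio of 299 with a 95% counting interval of 82.4 to 2471. Its fitted log2 fold change, which depends on the prior count, was 7.77 ± 2.17 SE and 5.93 ± 2.41 SE with the cluster as a term (adjusted p = 0.202). Over the alternatives the adjusted p ran from 0.00235 to 0.281. The number of changed models was 452 with the cluster as a term, 244 without the 8 larvae low on the second component, and 416 with no filter on low counts.

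The models that changed with age overlapped between regimes, which share no larvae. Day-night and constant-dark larvae shared 666 risen models, where lists independent of each other would share 132, and 1003 fallen models, where 182 would be shared. Day-night and constant-light larvae shared 218 risen models against 37.1 and 355 fallen models against 59.8. Constant-dark and constant-light larvae shared 190 risen models against 35.02 and 351 fallen models against 52.4. In all 3 regimes 153 models rose and 307 fell. Of the 3127 models called in day-night larvae, 93.0% had the same direction in constant dark and 84.6% in constant light.

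**Figure D2:**
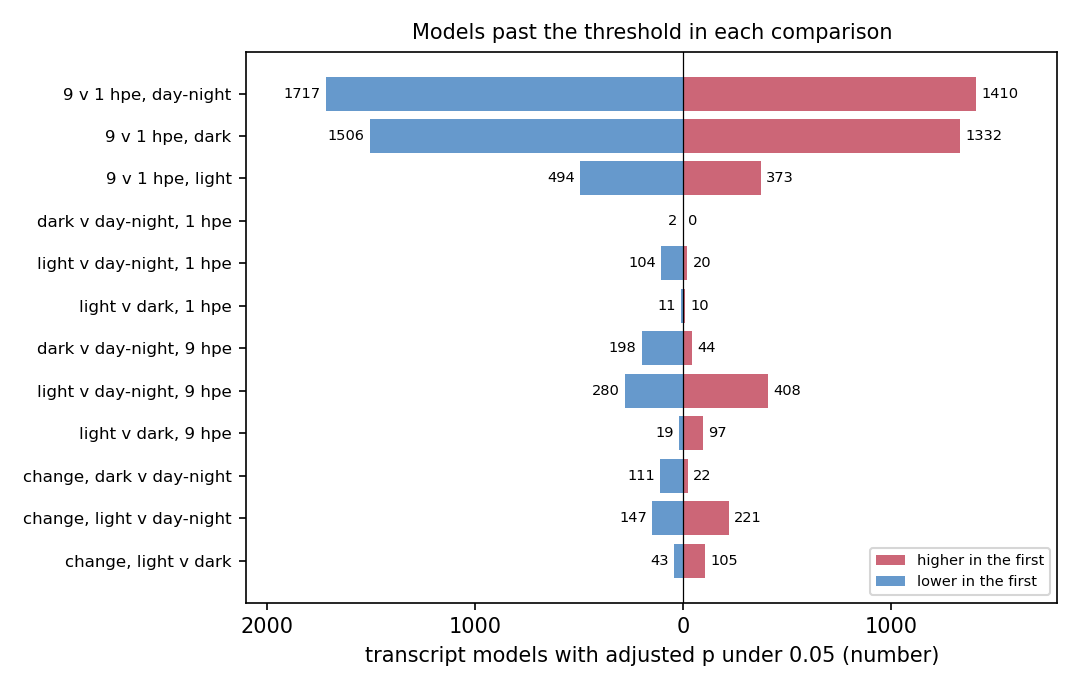
Number of models with an adjusted p below 0.05 in each of the 12 comparisons (horizontal axis), to the right where the first-named group was higher and to the left where it was lower. The bottom 3 bars count models whose change from 1 to 9 hpe differed between 2 regimes. Age changes in day-night larvae (1410 and 1717) and in constant dark (1332 and 1506) are larger in number than in constant light (373 and 494).

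At 1 hpe, constant-dark and day-night larvae differed in 2 models, both lower in constant dark. One was Aqu2.1.41011_001, with 68.3 ± 25.7 CPM in constant dark (n = 7) and 180 ± 22.1 CPM in day-night (n = 7), a log2 fold change of -1.40 ± 0.20 SE (edgeR adjusted p = 0.000447). Over the alternatives its adjusted p ran from 3.40e-08 to 0.149. Its level in constant light was 101 ± 18.2 CPM (n = 7). The other was Aqu2.1.33783_001, whose call rested on day-night replicate 1 with 459 CPM. Without that larva its log2 fold change was -0.78 and did not pass, and 1 model was left. The count was also 1 without any single one of constant-dark replicates 2 to 7. An unadjusted p below 0.05 was found for 1170 models, DESeq2 called 30, and 14 of 100 splits of these larvae, the real one included, called at least 2.

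Constant-light and day-night larvae at 1 hpe differed in 124 models, of which 104 were lower and 20 higher in constant light. Aqu2.1.33376_001 stood at 3.62 ± 2.29 CPM in constant light (n = 7) and 428 ± 546 CPM in day-night (n = 7), a log2 fold change of -6.87 ± 1.40 SE (edgeR adjusted p = 0.00824, and 6.00e-08 to 0.381 over the alternatives, the highest with limma voom). In constant-dark larvae, which shared the fit but were not compared in choosing them, the 104 models lower in constant light also fell with age. Their mean log2 CPM went from 5.79 at 1 hpe to 5.17 at 9 hpe there (exact two-sided permutation p = 0.000583, the smallest possible, adjusted p = 0.00126 over 13 such tests). Of the 104, 62 were called as fallen and 1 as risen in constant dark, where 11.0 and 9.76 would be by independent lists. The 20 models higher in constant light rose with age in constant dark, from 5.03 to 5.43 (exact permutation p = 0.000583, adjusted p = 0.00126). At 9 hpe the direction of those 20 had turned, with a difference of constant light from day-night of -0.12 (exact permutation p = 0.0157, adjusted p = 0.0291). For the 104 it was -0.16 (exact permutation p = 0.0545, adjusted p = 0.0702). The 124 became 36 without constant-light replicate 1 and day-night replicate 4, the most alike pair of larvae across regimes at that age, 70 without day-night replicate 4 alone, 71 with the cluster as a term, 21 with only the 2 groups in the fit, and 347 with DESeq2.

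Constant-light and constant-dark larvae at 1 hpe differed in 21 models, 10 higher and 11 lower in constant light. Aqu2.1.34611_001 stood at 61.9 ± 19.04 CPM in constant light (n = 7) and 161 ± 52.3 CPM in constant dark (n = 7). Its log2 fold change was -1.38 ± 0.21 SE (edgeR adjusted p = 0.00175, and 7.86e-07 to 0.0631 over the alternatives). In day-night larvae it stood at 95.3 ± 25.6 CPM at 1 hpe (n = 7), and at 9 hpe it stood at 811 ± 215 CPM in day-night, 637 ± 129 CPM in constant dark and 520 ± 149 CPM in constant light. The count of 21 became 3, 9, 9, 13, 7 and 6 without constant-dark replicates 1 to 6 in turn, 4, 9, 6 and 7 without constant-light replicates 1 to 4, and 11 and 10 without constant-light replicates 6 and 7. With the cluster as a term it was 2.

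At 9 hpe, 242 models differed between constant-dark and day-night larvae, and 198 of them were lower in constant dark. Aqu2.1.36115_001 had no count in any of the 7 constant-dark larvae and 33.2 ± 25.1 CPM in day-night larvae (n = 8, edgeR adjusted p = 4.64e-05), which puts it at least 213-fold lower in constant dark. Aqu2.1.21224_001 stood at 0.678 ± 1.31 CPM in constant dark and 77.4 ± 32.9 CPM in day-night, a log2 fold change of -6.89 ± 0.80 SE (adjusted p = 6.11e-08), and at or below 1.25 CPM on average in every group at 1 hpe. Of the 44 higher models, Aqu2.1.08473_001 stood at 35.4 ± 84.8 CPM in constant dark and 0.414 ± 0.303 CPM in day-night. Its log2 fold change was 6.23 ± 1.31 SE (edgeR adjusted p = 0.00288), and 0.40 ± 1.35 SE with the cluster as a term (adjusted p = 0.986). Limma voom gave it an adjusted p of 0.590. Constant-light larvae, which shared the fit but were not compared in choosing the 198, also held more of them at 9 than at 1 hpe. The mean log2 CPM of the 198 there was 5.15 at 1 hpe and 5.72 at 9 hpe (exact two-sided permutation p = 0.000583, adjusted p = 0.00126). In constant light 72 were called as risen and 12 as fallen, where 5.21 and 6.89 would be by independent lists. Both counts lay above these expectations, which take no account of some models being easier to call than others. The direction therefore rests on the 72 against the 12. At 9 hpe the mean was 6.75 in day-night and 5.20 in constant dark, the groups that chose the models, so constant light lay between them. The 44 models higher in constant dark had means of 5.75 at 1 hpe and 5.61 at 9 hpe in constant light (exact permutation p = 0.0530, adjusted p = 0.0702). At 1 hpe the mean of the 198 was 5.16 in constant dark and 5.23 in day-night (exact permutation p = 0.0594, adjusted p = 0.0702). DESeq2 called 378 models, and the fit with the cluster as a term called 152, of which 135 were among the 242.

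**Figure D3:**
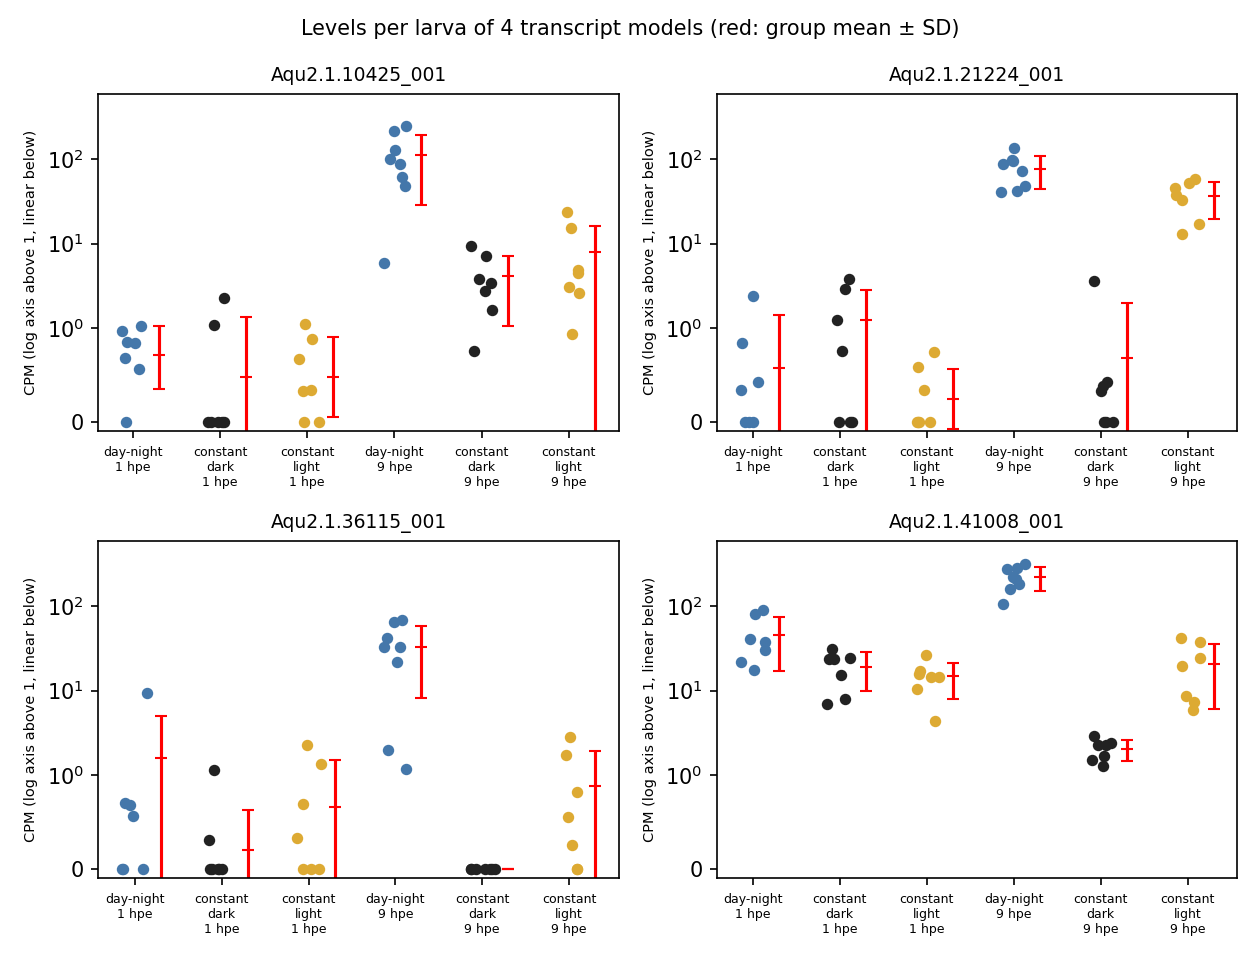
CPM of 4 models in each larva (vertical axis, logarithmic above 1 and linear below) for the 6 groups (horizontal axis), with the group mean and SD in red. These 4 models hold the 6 of 46 named results that kept their call in every alternative and with every larva left out. They are therefore not typical of the named models. Bars that would reach below 0 end at the lower edge. At 9 hpe day-night larvae average 112 CPM of Aqu2.1.10425_001, 77.4 of Aqu2.1.21224_001, 33.2 of Aqu2.1.36115_001 and 220 of Aqu2.1.41008_001, constant-dark larvae average 4.13, 0.678, 0 and 2.06, and constant-light larvae 7.86, 36.9, 0.882 and 20.8.

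Constant-light and day-night larvae at 9 hpe differed most among the comparisons of regimes at 1 age, in 688 models, with 408 higher and 280 lower in constant light. Aqu2.1.16391_001 stood at 86.9 ± 85.2 CPM in constant light (n = 7) and 0.832 ± 1.18 CPM in day-night (n = 8), a log2 fold change of 6.59 ± 1.74 SE (edgeR adjusted p = 0.0174). Aqu2.1.30516_001 stood at 0.241 ± 0.331 CPM in constant light and 90.3 ± 125 CPM in day-night, a log2 fold change of -8.44 ± 1.93 SE (adjusted p = 0.00508). The cluster term made these 5.33 ± 2.56 SE (adjusted p = 0.389) and -6.06 ± 2.50 SE (adjusted p = 0.280). Over the alternatives the adjusted p ran from 0.000187 to 0.517 and from 1.05e-05 to 0.525, the highest with limma voom. The 408 models higher in constant light fell with age in constant-dark larvae, which shared the fit but were not compared in choosing them. The mean log2 CPM of the 408 went from 6.90 at 1 hpe to 6.17 at 9 hpe there (exact two-sided permutation p = 0.000583, adjusted p = 0.00126). Of them, 228 were called as fallen and 9 as risen there, where 43.3 and 38.3 would be by independent lists. The 280 models lower in constant light rose with age in constant dark, from 4.53 to 4.87 (exact permutation p = 0.000583, adjusted p = 0.00126). Of the 280, 80 were called as risen and 23 as fallen there, against 26.3 and 29.7. At 1 hpe the 408 models averaged 6.80 in constant light and 6.79 in day-night (exact permutation p = 0.805). The 280 averaged 4.59 and 4.65 (exact permutation p = 0.0355, adjusted p = 0.0578). The 688 became 293 with the cluster as a term, 255 without the 8 larvae low on the second component, 429 with surrogate variables, 430 with only the 2 groups in the fit and 417 with no filter on low counts. The 8 larvae include 4 of the 7 constant-light larvae at 9 hpe, so for the 255 the smaller group cannot be told apart from the loss of alike larvae.

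Constant-light and constant-dark larvae at 9 hpe differed in 116 models, 97 higher and 19 lower in constant light. Aqu2.1.21224_001 was among the higher ones at 36.9 ± 17.1 CPM (n = 7) against 0.678 ± 1.31 CPM (n = 7), a log2 fold change of 5.82 ± 0.78 SE (edgeR adjusted p = 8.32e-06). Aqu2.1.18494_001 had 2 counts in all in constant dark and 30.4 ± 15.9 CPM in constant light (adjusted p = 0.0197), a ratio of 283 with a 95% counting interval of 78.0 to 2340. Its fitted log2 fold change, which depends on the prior count, was 7.69 ± 1.77 SE and 6.16 ± 2.75 SE with the cluster as a term (adjusted p = 0.514). Limma voom gave an adjusted p of 0.476 (0.000104 to 0.514 over the alternatives). Aqu2.1.31817_001 stood at 1.69 ± 0.584 CPM in constant light and 33 ± 19.1 CPM in constant dark, a log2 fold change of -4.26 ± 0.84 SE (adjusted p = 0.00426). The cluster term made it -3.86 ± 1.07 SE (adjusted p = 0.154), close in size with a larger error, and limma voom gave an adjusted p of 0.350 (2.16e-06 to 0.350 over the alternatives). Day-night larvae shared the fit but were not compared in choosing the 97 and the 19. There the 97 models fell with age from a mean log2 CPM of 7.25 to 6.68 (exact two-sided permutation p = 0.000311, adjusted p = 0.00126). The 19 had means of 3.11 and 3.31 there (exact permutation p = 0.108, adjusted p = 0.118). The count of 116 became 77 without constant-light replicate 7, 200 without constant-dark replicate 1, 198 without constant-light replicate 5, 35 with the cluster as a term, 22 with only the 2 groups in the fit and 305 with DESeq2.

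The change from 1 to 9 hpe differed between constant-dark and day-night larvae for 133 models, of which 111 changed less upwards, or more downwards, in constant dark. Aqu2.1.41008_001 went from 45.4 ± 28.3 to 220 ± 70.2 CPM in day-night larvae (n = 7 and 8) and from 19.1 ± 9.18 to 2.06 ± 0.579 CPM in constant dark (n = 7 and 7), a log2 difference of the changes of -5.47 ± 0.61 SE (edgeR adjusted p = 8.99e-08). In constant light it stood at 14.7 ± 6.67 CPM at 1 hpe and 20.8 ± 14.8 CPM at 9 hpe (n = 7 and 7). The difference of the changes was -8.01 ± 1.15 SE for Aqu2.1.21224_001 (adjusted p = 1.62e-05). With the cluster as a term 66 models were called, 58 of them among the 133, and both of these models were called with adjusted p of 3.85e-05 and 0.0193 (over the alternatives 1.33e-16 to 0.000141 and 6.80e-11 to 0.0193). Aqu2.1.08473_001 had the largest positive difference, 9.82 ± 1.78 SE (adjusted p = 0.000761), which was 6.49 without constant-dark replicate 5 at 9 hpe and 2.57 ± 2.13 SE with the cluster as a term (adjusted p = 0.908). Limma voom gave it an adjusted p of 0.4932 (3.73e-07 to 0.908 over the alternatives).

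The change with age differed between constant-light and day-night larvae for 368 models, 221 with a higher and 147 with a lower change in constant light. Aqu2.1.33376_001, which fell in day-night larvae, went from 3.62 ± 2.29 to 52.9 ± 85.0 CPM in constant light (n = 7 and 7), and its difference of the changes was 9.75 ± 1.78 SE (edgeR adjusted p = 0.00105, 0.0237 with the cluster as a term, and 7.93e-09 to 0.353 over the alternatives, the highest with limma voom). The differences for Aqu2.1.06761_001, 8.56 ± 1.99 SE (adjusted p = 0.0117), and Aqu2.1.31817_001, -4.52 ± 1.06 SE (adjusted p = 0.0125), were 5.56 ± 3.04 SE and -3.75 ± 1.25 SE with that term (adjusted p = 0.465 and 0.158). Over the alternatives the adjusted p ran from 5.15e-05 to 0.508 and from 0.000543 to 0.342, the highest with limma voom. The 368 became 198 with the cluster as a term, 142 without the 8 larvae low on the second component, 226 without the alike pair at 1 hpe, 146 with no filter and 611 with DESeq2.

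Between constant-light and constant-dark larvae the change with age differed for 148 models, 105 with a higher and 43 with a lower change in constant light. Aqu2.1.15450_001 went from 1.05 ± 0.676 to 54.2 ± 64.0 CPM in constant light (n = 7 and 7) and from 45.6 ± 81.7 to 1.28 ± 1.10 CPM in constant dark (n = 7 and 7), a difference of the changes of 10.77 ± 1.77 SE (edgeR adjusted p = 0.000532). Aqu2.1.44088_001 went from 52.7 ± 60.5 to 2.52 ± 1.57 CPM in constant light and from 1.37 ± 0.665 to 24.7 ± 28.9 CPM in constant dark, a difference of -8.47 ± 1.75 SE (adjusted p = 0.0104). With the cluster as a term the first stayed close in size with a larger error, 9.96 ± 2.46 SE (adjusted p = 0.152), while the second was -3.21 ± 2.06 SE (adjusted p = 0.702). That fit called 13 models, 11 of them among the 148. Limma voom gave adjusted p of 0.148 and 0.153 (over the alternatives 2.68e-10 to 0.171 and 6.98e-06 to 0.702). Without single larvae at 1 hpe the count was 92 (constant-dark replicate 6), 85, 82 and 94 (constant-light replicates 1, 2 and 3). Without single larvae at 9 hpe it was 252 and 79 (constant-dark replicates 1 and 4), 84, 232 and 81 (constant-light replicates 2, 5 and 7).

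The age score put these changes on 1 scale per larva, with the models taken from the regime left out of each comparison. With the 2838 models called in constant dark, the score of day-night larvae rose from -2.32 ± 0.265 (n = 7) to -0.84 ± 0.118 (n = 8) and that of constant-light larvae from -1.96 ± 0.151 (n = 7) to -1.26 ± 0.221 (n = 7). The rise in constant light, 0.69, was 47.0% of the rise of 1.48 in day-night larvae (exact two-sided permutation p of the difference = 1.61e-05, adjusted p = 4.84e-05 over 3 tests). Constant-light larvae lay above day-night larvae at 1 hpe by 0.36 (exact permutation p = 0.0146, adjusted p = 0.0219) and differed from them by -0.43 at 9 hpe (exact permutation p = 0.000311, adjusted p = 0.000466). With the 867 models called in constant light, the score of constant-dark larvae rose by 1.39, which was 73.0% of the rise of 1.91 in day-night larvae (exact permutation p = 6.72e-05, adjusted p = 9.85e-05). At 9 hpe constant-dark larvae differed from day-night larvae by -0.33 (exact permutation p = 0.000155, the smallest possible, adjusted p = 0.000466) and by 0.18 at 1 hpe (exact permutation p = 0.0775, adjusted p = 0.0775). With the 3127 models called in day-night larvae, the rise in constant light, 0.78, was 59.95% of the rise of 1.30 in constant dark (exact permutation p = 9.85e-05, adjusted p = 9.85e-05). Constant-light larvae lay above constant-dark larvae at 1 hpe by 0.27 (exact permutation p = 0.00175, adjusted p = 0.00524). They differed from them by -0.25 at 9 hpe (exact permutation p = 0.0198, adjusted p = 0.0198).

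**Figure D4:**
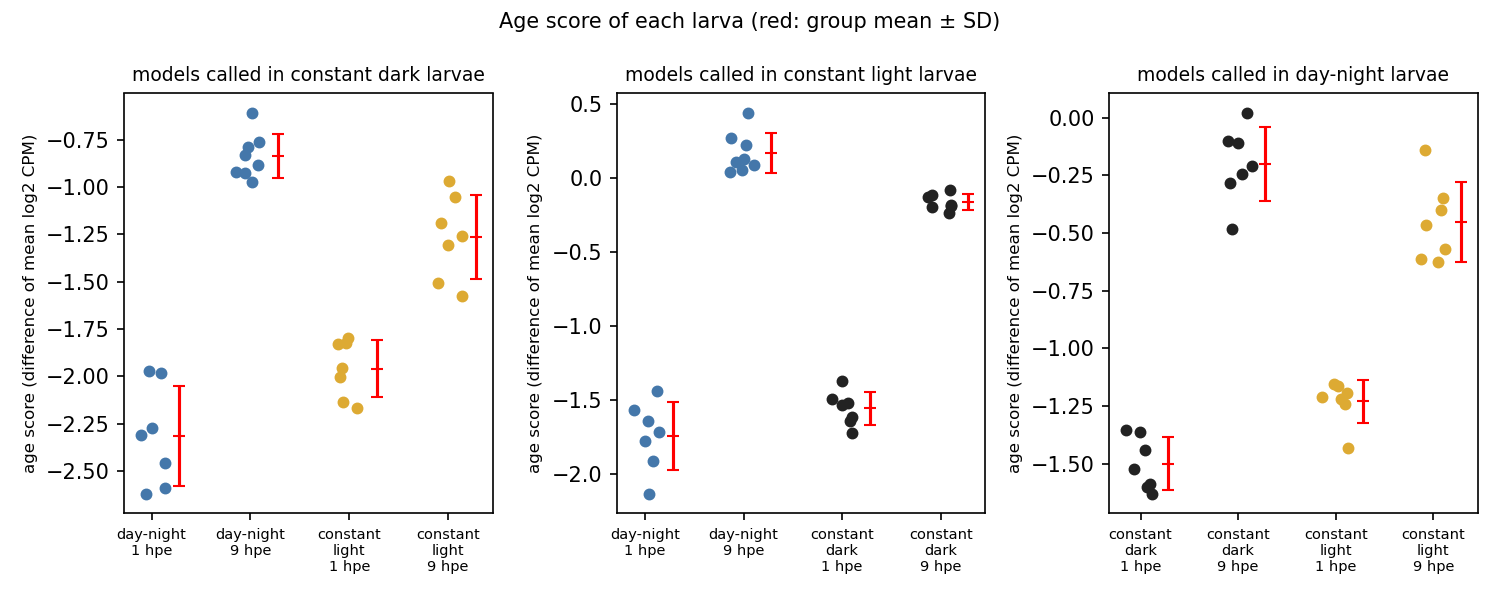
Age score of each larva (vertical axis, difference of mean log2 CPM between models higher and models lower at 9 hpe) by regime and age (horizontal axis), with the group mean and SD in red. Each panel uses models called with age in the regime it does not show. At 9 hpe the constant-light larvae average -1.26 and the day-night larvae -0.84 in the left panel, and the constant-dark larvae average -0.16 and the day-night larvae 0.17 in the middle panel.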

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

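The age score, the clusters of alike larvae and the tests with the cluster as a term were chosen after the results were seen. The other tests on depth and on the ceiling of the counts were written down before their values were known. The depth test for the models lower in constant dark was not, and for the comparison of depth between clusters this is not known.

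Differences between regimes in the change with age were found by tests of the difference itself. The change from 1 to 9 hpe differed for 133 models between constant dark and day-night, for 368 between constant light and day-night and for 148 between constant light and constant dark. The change of the age score differed by -0.78 between constant light and day-night, by -0.52 between constant dark and day-night and by -0.52 between constant light and constant dark.

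The first pattern weighed is the smaller change of the age score in constant light. Deeper libraries at 9 hpe are excluded as the whole cause, since the change was still 47.5% of the day-night change with counts thinned to 1 total per larva (exact permutation p = 2.1e-05). The ceiling on the counts of abundant models is excluded likewise, with 46.6% when those models were left out. With the cluster as a term the difference of the changes was -0.75 ± 0.180 SE, against -0.78 ± 0.145 SE without it. At 9 hpe constant-light and day-night larvae shared only the cluster with 2 larvae of each. The term therefore leans on the larvae at 1 hpe and assumes that a cluster shifts the score equally in each group. Under that assumption the uneven spread of these clusters over the groups is not the whole cause. The clusters came from the same data with only age means removed, so the term cannot exclude mothers or batches that the labels do not give. That the light regime alters the change with age is a hypothesis that may account for the -0.75. Age cannot be told apart from time of day here, so either may lie behind that change. A delay alone does not predict that constant-light larvae already lay 0.36 above day-night larvae at 1 hpe (exact permutation p = 0.0146, adjusted p = 0.0219).

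The second pattern is that larvae formed 9 clusters of at least 2 alike larvae, 7 of which hold more than 1 regime, while 3 larvae joined no other. Clusters from thinned counts had an adjusted Rand index of 0.954 with those from all counts, which excludes differences in depth. Clusters without the 579 most abundant models had an index of 0.787, which excludes the ceiling. No biological explanation was tested, since the labels give no parent for any larva. Shared mothers could produce such clusters, which the values of 0.954 and 0.787 neither favour nor exclude.

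The third pattern is the 198 models lower in constant dark than in day-night larvae at 9 hpe. With the cluster as a term the median ratio of their log2 fold changes to those without it was 1.0103 (lower quartile 0.901), and 119 of them were still called. With thinned counts the ratio was 0.994 and 175 were still called. Mean totals of constant dark and day-night at 9 hpe were nearly equal (2508172 and 2489125), which leaves little room for depth. Thinning could therefore hardly have moved the ratio, and it adds little on depth. At 9 hpe these 2 groups shared only the cluster with 2 larvae of each. The cluster term therefore leans on the other groups and assumes that a cluster shifts a model equally in each. Under that assumption the uneven spread of these clusters is not the whole cause. The clusters came from the same data, so mothers or batches that the labels do not give are not excluded. That the regimes alter these models is a hypothesis that the ratios of 1.0103 and 0.994 leave open. The difference from day-night may not be particular to constant dark. At 9 hpe the models averaged 5.72 in constant light, 5.20 in constant dark and 6.75 in day-night. That difference is partly built in, because the last 2 groups chose the models.

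Among 139 groups of values tested, 29 held a single larva far from the others. Chance gives about 1 in 20, but 21 of the 29 are groups of named models, which were picked for the largest fold changes, and that favours models carried by 1 larva, so the rate does not apply to them. Among library totals this was constant-dark replicate 7 at 9 hpe with 3485926 counts. Among age scores it was constant-light replicate 6 at 1 hpe with -1.43 (models from day-night larvae). Among mean log2 CPM of groups of models, those higher in constant dark than day-night at 9 hpe gave constant-light replicate 7 at 9 hpe with 5.88. Those higher in constant light than constant dark at 9 hpe gave day-night replicate 7 at 1 hpe with 7.02. Those lower in constant light than day-night at 1 hpe gave constant-dark replicate 1 at 1 hpe with 5.997 and day-night replicate 5 at 9 hpe with 5.01. Those higher in that comparison gave constant-dark replicate 6 at 1 hpe with 4.90 and day-night replicate 1 at 9 hpe with 5.19.

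Among named models the larva far from the others held these levels in CPM. In day-night larvae at 1 hpe these were 459 of Aqu2.1.33783_001 (replicate 1), 2.42 of Aqu2.1.21224_001 (replicate 4), 111 of Aqu2.1.06761_001 (replicate 5) and 104 of Aqu2.1.43252_001 (replicate 6). In constant dark at 1 hpe they were 4.54 of Aqu2.1.08473_001 (replicate 7), 371 of Aqu2.1.39570_001 and 9.46 of Aqu2.1.31641_001 (both replicate 6), and 228 of Aqu2.1.15450_001 (replicate 3). In constant light at 1 hpe they were 1145 of Aqu2.1.23654_001 and 209 of Aqu2.1.31641_001 (both replicate 6), and 2.98 of Aqu2.1.06761_001 (replicate 3). In day-night larvae at 9 hpe they were 22.2 of Aqu2.1.33376_001 and 382 of Aqu2.1.30516_001 (both replicate 8), 601 of Aqu2.1.23654_001 (replicate 1), 3.63 of Aqu2.1.16391_001 (replicate 3), 27.4 of Aqu2.1.15450_001 (replicate 4) and 4.95 of Aqu2.1.06761_001 (replicate 5). In constant dark at 9 hpe they were 227 of Aqu2.1.08473_001 (replicate 5) and 3.61 of Aqu2.1.21224_001 (replicate 6). In constant light at 9 hpe they were 0.566 of Aqu2.1.00322_001 and 55.8 of Aqu2.1.16039_001 (both replicate 4).

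Splits of the larvae into other groups, 100 per comparison with the real one included, called as many models as the real groups in 14 cases for constant dark against day-night at 1 hpe, so that its count of 2 cannot be told from chance. In each of the other 11 comparisons only 1 split, the real one, called as many.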

How the results depend on the processing

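The fits with the cluster, with surrogate variables, with corrected or thinned counts, and without certain larvae were chosen after the results were seen. DESeq2 size factors in edgeR, the mean of at least 10 CPM and the correction for the ceiling kept all 12 counts within 1.5 times, and no library fell under 0.5 times the median total. Counts below are in the order of the report, and where a count moved by over 1.5 times the cause was not tested. With the cluster as a term the 12 counts were 2059, 1087, 452, 1, 71, 2, 152, 293, 35, 66, 198 and 13. The fold changes of the called models moved less with the cluster term: their median ratio to those without the term ran from 0.905 to 1.03 in 11 comparisons and was 0.769 for the 2 models of dark against day-night at 1 hpe. With surrogate variables they were, for age in day-night, constant dark and constant light, 811, 379 and 267; at 1 hpe 1 (dark against day-night), 32 (light against day-night) and 1 (light against dark); at 9 hpe 429 (light against day-night) and 55 (light against dark); and for the differences of the age change 170 (light and day-night) and 17 (light and dark). These terms also shrank the fold changes with age, to a median ratio of 0.764 in day-night (2961 of 3127 in the same direction) and 0.685 in dark (2660 of 2838). Without the 8 larvae low on the second component they were 1732 and 244 (age in dark and light), 0, 71 and 1 (at 1 hpe), 255 and 39 (light against day-night and dark at 9 hpe), and 142 and 22 (differences of the age change with light). Those fits lost 4 of the 7 light larvae at 9 hpe and 3 of the 7 dark larvae at 1 hpe. Smaller groups cannot be told apart there from the loss of alike larvae. With no filter the counts were 416 (age in light), 1, 40 and 1 (at 1 hpe), 417 (light against day-night at 9 hpe), 146 and 61 (differences with light). With only the groups compared they were 576 (age in light), 0, 21 and 7 (at 1 hpe), 430 and 22 (light against day-night and dark at 9 hpe). DESeq2 gave 30, 347 and 117 (at 1 hpe), 378 (dark against day-night at 9 hpe), 305 (light against dark at 9 hpe), 611 and 430 (differences with light). Limma voom gave 1 (dark against day-night at 1 hpe). Without the alike pair at 1 hpe they were 36 and 7 (light against day-night and dark at 1 hpe), 226 and 78 (differences with light), and with thinned counts 13 (light against dark at 1 hpe) and 89 (difference of light and dark).

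The replicate block gave 1 (dark against day-night at 1 hpe), 6 (light against dark at 1 hpe), 233 and 92 (differences with light), and changed no other count by over 1.5 times. The numbers do not pair the larvae: same-numbered larvae had a mean correlation of -0.0056 against 0.000885 for others, 4 of 105 pairs exceeded 0.1, and 4 of 43 larvae correlated best with their own number. Leaving out each larva in turn gave 1 to 3, 70 to 173 and 3 to 16 models at 1 hpe, 77 to 200 for light against dark at 9 hpe and 79 to 252 for the difference of light and dark; other counts stayed within 1.5 times. Adjusted p of library totals of light at 9 hpe against day-night and dark became 0.0551 on untransformed totals. Of 46 named results, 24 kept their call with every larva left out, 12 with the cluster as a term and 11 with both, 38 lost it with limma voom, and 6 kept it in every alternative. The log2 fold change of Aqu2.1.08473_001 reversed with the cluster as a term, to -1.33 with age in constant dark and 1.40 for light against dark at 9 hpe, and that of TCONS_00000881 to -1.16 with age in constant light without the 8 larvae. The alternatives planned for gene lists were not run, since no identifier matched a gene name. What depth limits was not tested; over all models, 40% of simulated 2-fold age changes in day-night larvae were recovered.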

Other observations

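The clusters of alike larvae, the counts of neighbouring models and the comparison of model types were chosen after the results were seen. There were 9 clusters of at least 2 larvae, and 3 larvae joined no other. Of the 9, 7 held at least 3 larvae and 36 larvae in all, and each of these 7 held larvae of at least 2 regimes. Clusters hold both ages in 6 of these 7, which the removal of age means before clustering favours. For clusters formed from odd-numbered models, the mean correlation in even-numbered models was 0.201 within and -0.0471 between them. Clusters formed from odd and from even models had an adjusted Rand index of 0.548. A minimum of 10 CPM gave an index of 0.890 with the clusters used, and 1000 models with group means removed gave 0.601. Tests of membership against regime (permutation p = 0.0711) and larva number (permutation p = 0.797) did not pass. The closest pairs were constant-dark replicates 2 and 3 at 9 hpe (correlation 0.504), constant-light replicate 1 and day-night replicate 4 at 1 hpe (0.435), and constant-light replicate 7 at 1 hpe and replicate 5 at 9 hpe (0.403).

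Models with neighbouring numbers were called together more often than in shuffled lists in 9 of 12 comparisons (p below 0.05). At 1 hpe constant light against day-night had 2 such pairs (permutation p = 0.0849), and the other 2 comparisons of regimes at that age, with 2 and 21 models called, had 0 pairs against shuffled means of 0 and 0.008. Among 7934 neighbouring pairs, 389 were called in the same direction with age in day-night larvae, where 1000 shuffles gave a mean of 198 and at most 239. For constant dark against day-night at 9 hpe there were 20 such pairs against a mean of 1.63 and at most 7. In 105 neighbouring pairs the residual correlation exceeded 0.8, against 0 random pairs, and whether such pairs are copies of 1 transcript was not tested. Of the 363 tested models with TCONS identifiers, 13.8% changed with age in day-night larvae against 22.3% of the others (Fisher's exact test, adjusted p = 0.000393 over 12 comparisons). For constant light against day-night at 9 hpe these were 1.65% and 4.93% (adjusted p = 0.00727). The test of the share passed in 4 of 12 comparisons and did not pass in the other 8. It takes models as independent, though neighbouring ones were called together, and takes no account of abundance. The shares therefore do not show that TCONS models respond less. For constant light against constant dark at 9 hpe the share was 1.10% against 0.810%.

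Among 33 models whose mean lay at or above 0.5 times the highest count, the median log2 fold change with age was -0.31 in day-night, -0.44 in constant dark and -0.34 in constant light, and -0.76, -1.17 and -0.64 after correction for the ceiling. Of these models 13 of the 15 called in day-night larvae, 22 of 23 in constant dark and 8 of 8 in constant light were lower at 9 hpe.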
